A study of Rattus norvegicus with 8 samples.

How the data were processed

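RNA was sequenced from 8 libraries of primary rat nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc. The cells came from Wistar rats, were grown out of tissue explants and were transduced with lentivirus carrying a short hairpin RNA. In 4 libraries the hairpin had no target (ShCTR) and in 4 it was directed against HuR (ShHuR), the RNA-binding protein encoded by Elavl1. Every culture was held at 1% oxygen for the last 24 h. Ribosomal RNA was depleted and stranded total-RNA libraries were made, per the labels' protocols. The aligner, the counting program, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed, and whether reads were counted by strand is unknown. Overlapping genes, antisense genes and genes with processed pseudogenes are therefore uncertain.

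The deposited values per library are a normalized signal: gene counts that the authors divided by 1 factor per library, as read from the values and from the word normalized in the file headers. In each column 100% of the values were whole multiples of the column's step, to within 0.01 read, so the reads behind them were recovered. The step of the ShHuR replicate 2 column lies so close to 1 that the automatic test of whole reads cannot apply to that column. Recovered totals ran from 6797360 to 12179515 reads per library. The table holds 13536 rows, of which 4 were at 0 in every library. The authors also deposited log2 fold changes with adjusted p-values, and the file headers (baseMean, lfcSE, padj) are the column names that DESeq2 writes. Their table calls 2116 genes, 1058 higher and 1058 lower. A positive log2 value there is higher in ShHuR, as the per-library columns show.

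In the sheet of all genes the Ensembl identifiers stand out of register with the symbols. Of 2116 rows matched by their values to the sheet of called genes, 2115 had the same symbol and 3 the same identifier. Symbols were therefore used as row names, and identifiers were taken only from the sheet of called genes. A spreadsheet had turned 21 symbols into dates. Those rows, with 0.258% of the reads, were treated as unnamed and stayed out of the naming of genes. Of the symbols, 11706 were found in a table of RefSeq genes for the GRCr8 assembly and 609 only as a synonym there.

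Values were analysed as log2(value + 1), and a fold change is on that scale, which understates the change of low genes. A row was tested when at least 4 of the 8 libraries reached 10 normalized counts, which left 11847 rows and dropped 1689. The test was limma 3.58.1 with a mean-variance trend in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test, its samples, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The fit fixed as the main one had no block for replicate number. Replicate agreement was checked with a chi-square per degree of freedom on the recovered reads of genes with at least 20 reads. It lay between 43.5 and 188.5 within groups, so no 2 libraries of the same group agreed within sampling noise.

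Both groups carry replicate numbers 1 to 4 in the labels. The numbers were taken to pair the libraries if every same-numbered pair of libraries deviated together from the group means, with a correlation over 0.1, and this was decided before the calls of the fits were compared. The correlations across genes were 0.87, 0.78, 0.63 and 0.77 for numbers 1 to 4, and each library correlated best with its own number. ShCTR replicate 3 did so only narrowly, since its correlation with ShHuR replicate 2 was 0.62. Replicate number held 76.4% of the sum of squares over the tested genes and group 14.7%. Replicate number has more levels than group and so takes up more by chance. Neither share is the size of the knockdown effect. The first principal component, with 57.2% of the variance, set pair 1 apart from the other pairs. The pairing comes from these values and the shared numbers, since the labels do not say what a number stands for. The file headers repeat the number in a tag shared by both groups. Libraries that share a tag have adjacent identifiers there, again without a stated meaning. The fit with replicate number as a block is therefore printed beside the fit without it, and fold sizes, standard errors and adjusted p-values of single genes are from the blocked limma fit unless another is named. Because nothing says that the 4 libraries of a group came from separate animals or cultures, p-values measure only the spread between these samples.

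Named genes are Elavl1 and its paralogs, 17 genes fixed by name, the 10 largest rises and 10 largest falls, and up to 2 rising and 2 falling members of each fixed list. Some genes that the rule names are not reported here. The largest changes were taken among genes past the threshold, above the median of mean expression, whose 4 ShHuR values lay all above or all below the 4 ShCTR values. In the blocked fit 113 genes qualified as higher and 166 as lower, and without the block 0 and 0 did. If all libraries were exchangeable, 1 gene in 35 would by chance have 2 groups of 4 that do not overlap. Paired libraries are not, so this rate is only a rough guide. Gene lists with at least 5 tested members, 21 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

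Alternatives were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, pseudocounts of 0.5 and 8, no filter and a filter at 50, median-of-ratios scaling, quantile normalization, empirical Bayes without a trend or with robust estimation, and leaving out each library or pair. The procedure was tested on simulated data for the comparison of ShHuR with ShCTR over 11847 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Limma with the block recovered 82% of the 2-fold and 97% of the 4-fold changes with 17 false calls. Limma without the block recovered 1% and 46% with 0 false calls. Each simulated change had the same size in every pair, whereas the real changes differed between pairs, so these shares may not carry over. Camera called 0 of 21 lists when no list had been moved. The noise of the simulated genes was drawn independently, so this does not test false calls among lists with correlated members. Tables were prepared with Python 3.11.15 and pandas 2.3.3.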

Results

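The series asks which transcripts depend on HuR in hypoxic nucleus pulposus cells, with the extracellular matrix as its subject. HuR binds AU-rich elements of many mRNAs and is known to affect their stability and translation. There were 4 libraries with the non-target hairpin (ShCTR) and 4 with the hairpin against Elavl1 (ShHuR), all from cells kept at 1% oxygen for 24 h. Recovered reads were 11234610, 12179515, 10277875 and 9096738 in ShCTR replicates 1 to 4 and 6797360, 8038192, 7493728 and 7655461 in ShHuR replicates 1 to 4. The ShHuR libraries were shallower, at 7496185 ± 518814 reads against 10697184 ± 1319518 (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give).

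Elavl1 (ENSRNOG00000001069), the target, fell in each of the 4 pairs. Its normalized counts were 554.8, 699.3, 582.5 and 644.3 in ShCTR replicates 1 to 4 and 63.8, 6.1, 8.4 and 49.6 in ShHuR replicates 1 to 4. The means were 620.2 ± 64.6 and 31.96 ± 29.2 (SD, n = 4), a log2 fold change of −4.84 (SE 0.55). The share of the control level that remained was 11.5%, 0.867%, 1.43% and 7.7% in pairs 1 to 4. All ShHuR values lay below all ShCTR values (exact permutation test, two-sided, p = 0.0286). An exact sign-flip test of the 4 pairs, two-sided, gave p = 0.125, the smallest that 4 pairs can give. In limma the adjusted p was 0.00663 with the replicate block and 0.126 without it. With the block, leaving out pair 4 gave −5.23 in limma with an adjusted p of 0.0549. Elavl2, a paralog, was low and differed little, at 34.9 ± 27.1 against 39.1 ± 34.1 normalized counts (SD, n = 4; limma with the block, adjusted p = 0.976). Elavl3 and Elavl4 are not analysed here.

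**Figure D1:**
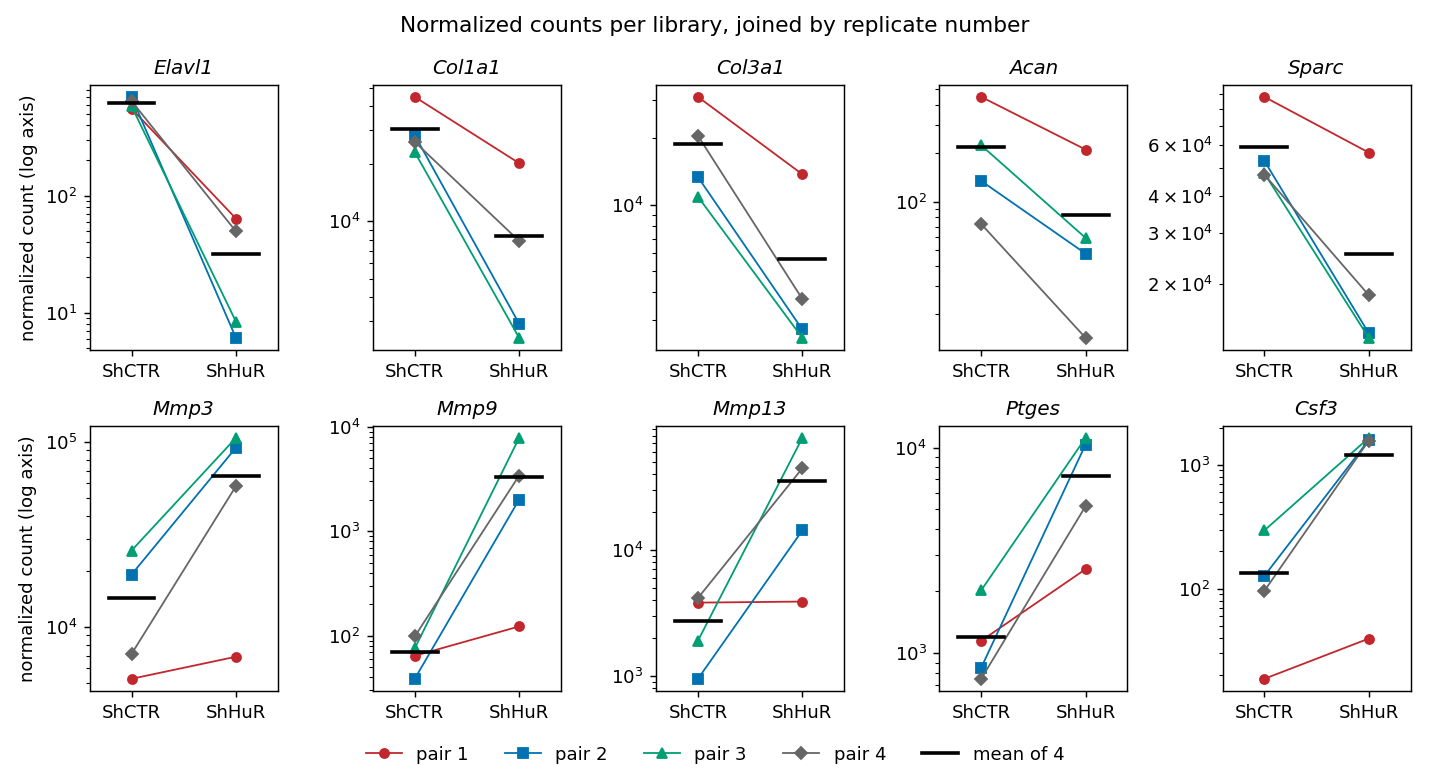
Normalized counts (log axis) of 10 genes in the 4 ShCTR and 4 ShHuR libraries, with the 2 libraries of a replicate number joined by a line and black bars for the group means. Elavl1 lay at 554.8 or above in every ShCTR library and at 63.8 or below in every ShHuR library, and the line of pair 1 is the flattest for Mmp9 and Mmp13.

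The 10 largest rises and 10 largest falls were ranked among called genes above the median of mean expression whose 4 ShHuR values lay all above or all below the 4 ShCTR values. Mmp9, a gelatinase, rose from 69.4 ± 24.9 to 3349 ± 3286 normalized counts (SD, n = 4), a log2 fold change of 4.59 (SE 0.80). The next rises under that rule were those of Tgm1, a transglutaminase, at 3.92, Crisp3, a cysteine-rich secretory protein, at 3.34, and Car4, a carbonic anhydrase, at 3.31. Ptges, which makes prostaglandin E2, rose by 2.50, the integrin gene Itgb8 by 2.44 and the spermine oxidase gene Smox by 2.34. Lcn2 (lipocalin 2), the Notch target Hes1 and the efflux transporter gene Slc47a1 rose by 1.80, 1.71 and 1.64. Under the same rule the falls after Elavl1 were those of Gnai1, an inhibitory G-protein subunit, at −3.04, Col1a1 at −2.35, Cisd1, a protein of the outer mitochondrial membrane, at −2.22, and Ctgf at −1.97. Sfrp4, a secreted Wnt modulator, fell by 1.81 and Cmtm4 fell by 1.75. The peptidase gene Prcp fell by 1.71, the ubiquitin ligase gene Mgrn1 fell by 1.67 and Hmox1, the inducible haem oxygenase, fell by 1.63. Adjusted p-values of these 20 genes in limma with the block lay between 0.00505 for Prcp and 0.0402 for Ctgf. Of the 20, 18 moved least in pair 1. There Mmp9 rose by 0.92, against 5.10 to 6.68 in the other pairs, Crisp3 by 0.61 against 3.03 to 5.66 and Car4 by 0.46 against 2.81 to 5.71, and Sfrp4 fell by 0.06 against 1.76 to 3.27. Pair by pair Ctgf moved by −0.52, −1.59, −4.09 and −1.68. Leaving out 1 pair moved the fold change of 5 of the 20 by more than 1.5 times: without pair 1 the log2 values of Mmp9, Crisp3 and Car4 were 5.81, 4.25 and 4.26, without pair 2 that of Elavl1 was −4.24, and without pair 3 that of Ctgf was −1.26.

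Limma with the replicate block called 1802 of 11847 genes changed, 848 higher and 954 lower in ShHuR. Limma without the block, the fit chosen as the main one, called 0 genes, with 978 at an unadjusted p under 0.05 and a smallest adjusted p of 0.126. Without the block edgeR called 0 genes, with 1010 under 0.05, and DESeq2 called 248, 108 higher and 140 lower. With the block edgeR called 1845, DESeq2 2053, and limma without a mean-variance trend 573. The blocked count depended on which pairs were included. Limma called 2831 genes without pair 1, 62 without pair 2, 523 without pair 3 and 0 without pair 4. At an unadjusted p under 0.05 blocked limma had 4089 genes with all pairs. Without pairs 1, 2, 3 and 4 in turn it had 4642, 2776, 2969 and 2937. EdgeR called 164 without pair 4. Every "rose" or "fell" of a single gene refers to the fit with all 4 pairs. Of 21 gene lists camera called 7 with the block, 4 without it and 0 with an estimated correlation. With the block and without pair 1 it called 12, the same 7 and 5 more: HIF-1 targets and glycolysis, mitochondrially encoded genes, histones, AU-rich element binding proteins, and enzymes of collagen and glycosaminoglycan synthesis. With an estimated correlation and without pair 1 it called 0. With the block and all pairs, an estimated correlation gave most lists the same adjusted p of 0.555 in camera. That includes AU-rich element binding proteins, estimated at 0.0105, whose adjusted p at the preset 0.01 was 0.0827. It also includes pH and ion homeostasis, estimated at 0.00249, with 0.159 at the preset. A call lost under this setting therefore does not measure correlation among the members alone. Fry, which does not compare a list with other genes, called 0 lists in 1 direction and 18 in either direction.

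More collagen genes fell than rose. Of 26 tested collagens 12 fell and 2 rose, or 15 and 5 adjusted over the list alone, with a median log2 fold change of −0.61. Col1a1 went from 30490 ± 9757 to 8332 ± 8232 normalized counts (SD, n = 4), −2.35 with an SE of 0.37, and Col3a1 from 18890 ± 8964 to 5660 ± 5405, −2.02 with an SE of 0.22. These fibrillar collagens had adjusted p-values of 0.0127 and 0.00588 in limma with the block. Col4a2, a basement membrane collagen, rose by 0.73 and Col27a1 by 0.66. EdgeR with the block did not call Col4a2 (adjusted p = 0.051), and limma after quantile normalization did not call Col27a1. Col2a1, the main collagen of cartilage, was at 21 or below in every library and was not tested. Camera with the block gave the list an adjusted p of 0.00242, and 0.555 with an estimated correlation. Markers of annulus fibrosus and fibroblasts moved with the collagens: of 14 tested, 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera with the block, adjusted p = 0.00242, and 0.555 with an estimated correlation). That list holds Col1a1 and Col3a1, and the median of its 12 other members was −0.54. Among those, Pdgfrb fell by 0.78 and Twist2 rose by 1.45.

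Proteoglycans and link proteins showed 8 falls and 0 rises among 23 tested genes (8 and 1 adjusted over the list alone). Acan, which encodes aggrecan, the large proteoglycan that holds water in the disc, fell from 220.3 ± 164.9 to 83.1 ± 87.5 normalized counts (SD, n = 4), a log2 fold change of −1.69 (SE 0.21; limma with the block, adjusted p = 0.0085). The glypican gene Gpc1 fell by 1.27. Camera with the block gave this list an adjusted p of 0.02, which became 0.555 with an estimated correlation. Without the block its adjusted p in camera was 0.106, and without pair 3 it was 0.0628. Among 46 matrix glycoproteins 6 fell and 3 rose (6 and 3 adjusted over the list alone), and camera with the block did not call the list (adjusted p = 0.388). The tenascin gene Tnn fell by 2.49 and Sparc, a collagen-binding glycoprotein, by 1.47, while Tnxb rose by 1.49 and Fbn1, fibrillin 1, by 0.63.

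More matrix proteases and inhibitors rose than fell, with 10 of 40 higher and 2 lower (11 and 3 adjusted over the list alone). Mmp3, stromelysin 1, went from 14370 ± 9849 to 65670 ± 44050 normalized counts (SD, n = 4; log2 fold change 1.93, SE 0.39; limma with the block, adjusted p = 0.0224). Mmp13, collagenase 3, went from 2702 ± 1530 to 34870 ± 32950 (3.17, SE 0.71; limma with the block, adjusted p = 0.0289), but pair 1 moved by 0.03. The inhibitors Timp1 and Timp3 rose by 0.97 and 0.98, the latter with an adjusted p of 0.047 in limma with the block and no call after quantile normalization. Adamts7 rose by 1.11, whereas Adamts5, an aggrecanase, fell by 1.19 and Adam15 by 0.64. The log2 value of Adamts4, another aggrecanase, was 0.95, with an adjusted p of 0.0501 in limma with the block. The list median was 0.04, and camera with the block did not call the list (adjusted p = 0.379). Of 42 enzymes of collagen and glycosaminoglycan synthesis 4 rose and 6 fell (4 and 9 adjusted over the list alone; camera with the block, adjusted p = 0.0997, and 0.0457 without pair 1, with 3 higher and 12 lower, where an estimated correlation gave 0.552). Loxl2, a collagen cross-linking oxidase, and Crtap, needed for collagen prolyl hydroxylation, fell by 1.44 and 1.45. Bmp1, a procollagen C-proteinase, rose by 1.14 and the hyaluronidase gene Hyal2 by 0.53.

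Among 35 inflammation and NF-kB target genes 15 rose and 2 fell (21 and 3 adjusted over the list alone), with a median of 0.73. Csf3, a granulocyte growth factor, went from 134 ± 116.5 to 1210 ± 781.1 normalized counts (SD, n = 4; log2 fold change 2.79, SE 0.43; limma with the block, adjusted p = 0.0127). Ptges went from 1192 ± 577.4 to 7304 ± 4119. The chemokine genes Ccl7 and Cxcl12 fell by 1.24 and 1.29. Camera with the block gave an adjusted p of 0.000222, and 0.555 with an estimated correlation. The list median per pair was 0.08 in pair 1, 1.08 in pair 2, 0.65 in pair 3 and 1.41 in pair 4. Without pair 1, 22 members were higher and 2 lower. Of the leukocyte and macrophage markers 3 could be tested, and 0 passed, also adjusted over the list alone.

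**Figure D2:**
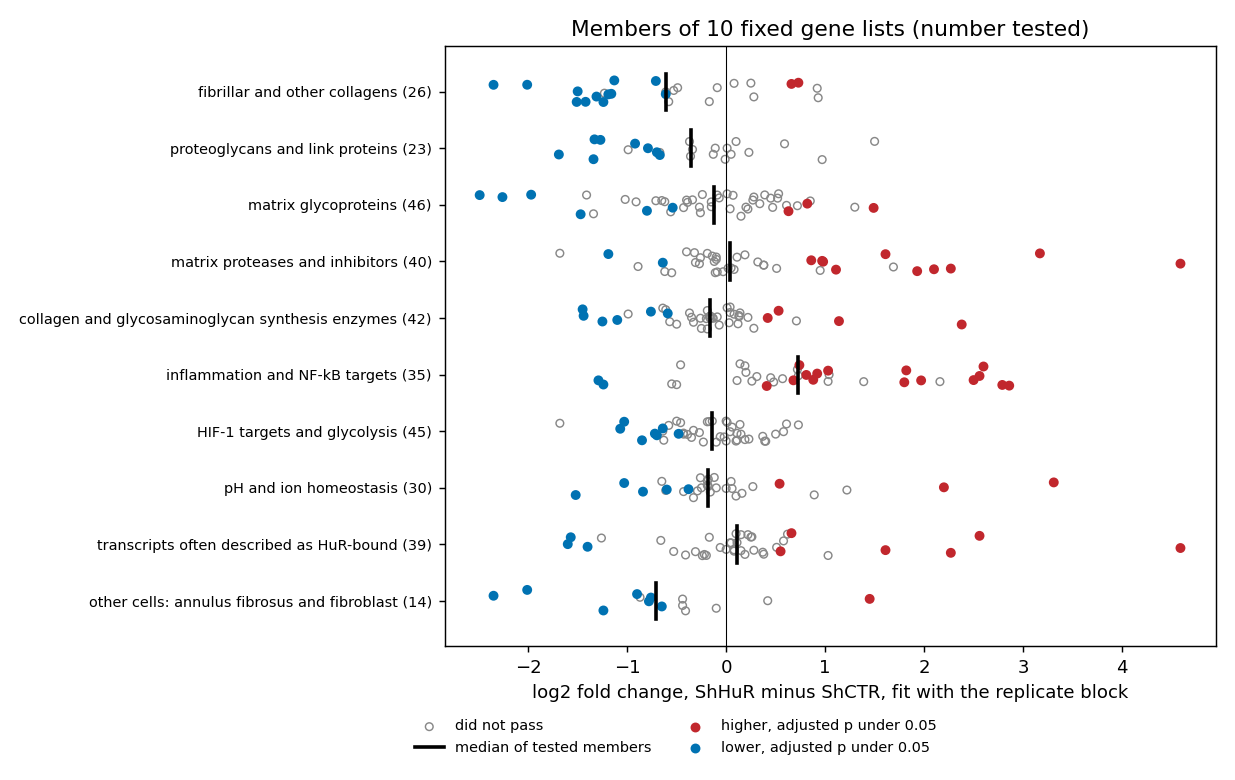
Log2 fold changes (ShHuR minus ShCTR, limma with the replicate block) of the tested members of 10 gene lists, 1 point per gene, filled where the adjusted p was under 0.05, with a black bar at each list's median. The collagen median was −0.61 and the inflammation median 0.73.

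Of 17 nucleus pulposus and notochord markers 2 fell and 0 rose (2 and 1 adjusted over the list alone, and 2 and 3 over all genes without pair 1). Camera with the block did not call this list (adjusted p = 0.367). Sox6, a chondrogenic transcription factor, fell by 1.09 and the carbonic anhydrase gene Car12 by 1.03. Sox9 was at 26.2 ± 13.2 and 20.9 ± 12.3 normalized counts (SD, n = 4; limma with the block, adjusted p = 0.366). T, Krt19 and Tnf are not analysed here. Among 45 HIF-1 targets and glycolytic genes 7 fell and 0 rose (9 and 2 adjusted over the list alone), and camera with the block did not call the list (adjusted p = 0.0829). Without pair 1, 17 fell and 3 rose and camera called the list, as lower (adjusted p = 0.0172, and 0.555 with an estimated correlation). Pfkm, muscle-type phosphofructokinase, fell by 1.07 and the adenylate kinase gene Ak4 by 0.64. Several genes central to the hypoxic response did not pass in limma with the block: Hif1a had a log2 value of 0.04 (SE 0.16, adjusted p = 0.87), Vegfa 0.11 (SE 0.15, adjusted p = 0.631), Slc2a1 0.58 (SE 0.23, adjusted p = 0.128) and Car9 −0.43 (SE 0.19, adjusted p = 0.149). Of 30 genes of pH and ion homeostasis 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera with the block, adjusted p = 0.159). The list median was −0.18 and its mean 0.02, and camera's direction was down. Car4 and Car8 rose by 3.31 and 2.20, and Atp1b1, a sodium pump subunit, and Car5b fell by 1.52 and 0.60.

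Of 39 transcripts often described as bound by HuR 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera with the block, adjusted p = 0.388). Actb, which encodes cytoplasmic beta-actin and has processed pseudogenes that could share its reads, fell from 35150 ± 9062 to 11800 ± 3909 normalized counts (SD, n = 4), −1.60 with an SE of 0.21 (limma with the block, adjusted p = 0.0102). Slc7a1, a cationic amino acid transporter, fell by 1.57, while the urokinase receptor gene Plaur rose by 1.61 and Prkcd by 0.66. Of 22 AU-rich element binding proteins 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera with the block, adjusted p = 0.0827, and 0.0457 without pair 1, with 5 higher and 0 lower, where an estimated correlation gave 0.541). Among them were Igf2bp3 at 0.71 and Hnrnpdl at 0.57, with Igf2bp2, named after its value was seen, at 1.63.

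Cell cycle genes included 5 falls and 1 rise among 52 (5 and 1 adjusted over the list alone, and 14 and 2 over all genes without pair 1). Camera with the block gave an adjusted p of 0.0117, without the block 0.242, and with an estimated correlation 0.555. Ndc80, a kinetochore gene, fell by 0.70, the ribonucleotide reductase gene Rrm1 by 0.53, and Cdk2 rose by 0.58. In the list of the unfolded protein and integrated stress response 5 of 33 fell and 3 rose (12 and 3 adjusted over the list alone, and 10 and 3 over all genes without pair 1). Camera with the block gave this list an adjusted p of 0.0322, and 0.555 with an estimated correlation. The chaperone gene Hyou1 fell by 0.87 and Herpud1 by 0.52, and the cystine transporter gene Slc7a11 rose by 1.98 and Sesn2 by 0.64. Of 26 contractile and YAP/SRF target genes 4 fell and 2 rose (5 and 2 adjusted over the list alone, and 9 and 2 over all genes without pair 1). For this list camera with the block gave an adjusted p of 0.0357, without the block 0.057, and with an estimated correlation 0.555. Cald1 and Acta2 fell by 1.38 and 0.91, and Myl9 and Zyx rose by 0.95 and 0.52.

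No list among p53 targets, interferon response and cholesterol synthesis passed camera with the block (adjusted p = 0.146, 0.388 and 0.483). Of 27 p53 targets 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Eda2r at 0.89 and Pmaip1 at −0.78. Of 29 interferon-response genes 3 rose and 3 fell (4 and 7 adjusted over the list alone), with Usp18 at 1.26, Irf1 at 0.99 and Ifit2 at −1.16. Of 25 cholesterol synthesis genes 1 rose and 2 fell (2 and 3 adjusted over the list alone), with Insig1 at 0.52, Srebf2 at −0.86 and Cyp51 at −0.76. Of 11 histone and 10 mitochondrially encoded genes 0 passed over all genes and 0 adjusted over the list alone (camera with the block, adjusted p = 0.128 and 0.483). Without pair 1, 2 of each fell and 0 rose, and camera called both lists (adjusted p = 0.0457 and 0.0267, and 0.555 for each with an estimated correlation). Among markers of other cells, Flt1 of 3 endothelial genes rose by 1.16 (1 higher and 0 lower adjusted over the list alone) and Pmp22 of 4 Schwann and neural genes fell by 1.16 (2 higher and 1 lower adjusted over the list alone). Mmp13 was the 1 of 5 hypertrophic cartilage and bone markers that passed (1 higher and 0 lower adjusted over the list alone). That list had a median of −0.28, a mean of 0.45 and an adjusted p of 0.939 in camera with the block. Of 2 skeletal muscle genes 0 passed, also adjusted over the list alone. Of 3 adipocyte and erythroid genes 0 passed over all genes, 2 were higher adjusted over the list alone (Fabp4 and Pparg, named after their values were seen), and edgeR with the block called 1 as higher, Fabp4.

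The authors' deposited table calls 2116 genes, and 2026 of these were among the rows tested here. Limma with the block called 1735 of the 2026, each with the same sign as in the authors' deposited table. The authors' deposited table gives Elavl1 a log2 fold change of −1.82 and an adjusted p of 3.96e-05, and Mmp9 1.39.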

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

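The comparison of each library with the rest of its group was planned. It was run over 178 groups of 4 values, those of the named genes and of the read totals. It singled out 5 values, where chance gives about 8.9 (1 in 20). No explanation was weighed for any single value.

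In the ShCTR group, Tgm1 was at 13.9 normalized counts in replicate 2 against 60.3 to 64.4 in the others, and Hnrnpdl was at 1387.9 in replicate 1 against 544.2 to 574.8. In the ShHuR group replicate 1 stood apart for 3 genes. Its value was 267.4 for Ak4 against 440.5 to 454.5, 39.5 for Csf3 against 1567.7 to 1649.3, and 118.5 for Ccl7 against 2616.5 to 2989.4. The other library of pair 1 lay on the same side. ShCTR replicate 1 was at 495 for Ak4 against 562.8 to 754.2, 18.7 for Csf3 against 95.9 to 294.9, and 364.3 for Ccl7 against 3211.8 to 11535.8. Hnrnpdl was at 2142.5 in ShHuR replicate 1 against 727.1 to 936.9. Tgm1 in ShHuR replicate 2, at 557.5, lay within the range of the others.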

How the results depend on the processing

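The blocked versions of the planned settings, thinning to equal depth, edgeR without single pairs and camera with the block and an estimated correlation, with all pairs or without pair 1, were chosen after the data were seen. A feature-level alternative was not run, because the rows are genes. The replicate block took the genes changed from 0 (978 at an unadjusted p under 0.05 in limma) to 1802 (848 higher, 954 lower), the lists past camera from 4 to 7, and Elavl1, at −4.84 in both, past the threshold. DESeq2 without the block called 248 genes (108 higher, 140 lower), with Elavl1 at −4.29. Leaving out 1 library without the block gave 0 to 105 genes (0 to 40 higher, 0 to 65 lower), the 105 without ShHuR replicate 1, 2 to 8 lists, and Elavl1 at −5.37 to −4.31, past the threshold without ShHuR replicate 1. The other settings without the block left 0 genes and 4 or 5 lists. With an estimated correlation camera called 0 lists, with or without the block, and 0 with the block and without pair 1. With the block, empirical Bayes without a trend called 573 genes (242 higher, 331 lower), and other settings with 4 pairs called between 1626 and 2053. Leaving out 1 pair, limma called from 0 genes without pair 4 (2937 at an unadjusted p under 0.05) to 2831 without pair 1 (0 to 1334 higher, 0 to 1497 lower), and 62 and 523 without pairs 2 and 3. EdgeR called 2803 without pair 1 (1300 higher, 1503 lower), 153 without pair 2 (80 and 73), 717 without pair 3 (299 and 418) and 164 without pair 4 (67 and 97). Lists past camera went from 5 to 12, and Elavl1 from −5.42 to −4.02, with −5.23 and an adjusted p of 0.0549 in limma without pair 4. Fewer pairs leave fewer degrees of freedom, and beyond that the cause was not tested. Elavl2 reversed to −0.006 under quantile normalization and Hif1a to −0.064 in edgeR and −0.044 in DESeq2, all without the block and short of the threshold. Without single libraries Elavl2 ranged from −0.496 to 0.456, Hif1a from −0.104 to 0.346, Vegfa from −0.278 to 0.524 and Insig1 from −0.235 to 1.326, none of them called. Of 81 named genes called with the block, 81 kept their sign and 79 their call under both other scalings, Col27a1 and Timp3 losing it under quantile normalization. Thinning every library to the shallowest total gave 1626 genes with the block, 1555 of them among the 1802. The lower totals of the ShHuR libraries limit the precision of genes with few reads there, such as Elavl1 with 6 reads in replicate 2.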

Other observations

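The integrin and reference-gene groups, the split count of genes without the block, the test of the HuR-bound list and the comparison of fibroblast markers with all tested collagens were chosen after their results were seen, as was reading the slope of pair 4 against the gap between pairs 2 and 3. Integrin genes, which encode receptors for matrix proteins, moved in both directions. Of 13 tested in limma with the block, 3 rose and 3 fell. Itgb8, Itga2 and Itga5, the latter a subunit of the fibronectin receptor, rose by 2.44, 1.77 and 1.20, each in 4 of 4 pairs. Itga11, a subunit of a collagen receptor, fell by 2.65, Itga1 fell by 0.67 and Itgb5 fell by 0.87, each in 4 of 4 pairs, and Itgb5 lost its call after quantile normalization. Itgb1, the subunit that pairs with many of these, was at 30500 normalized counts in ShCTR and 29700 in ShHuR.

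Of 16 genes often used as references in quantitative PCR, a set from which Pgam1, not a usual reference, was removed after it was seen to fall, 1 fell and 0 rose in limma with the block. It was Actb, which fell by 1.60 in 4 of 4 pairs and was called under each scaling tried. Rplp0, at 0.19 (SE 0.14), and Ywhaz, at −0.09 (SE 0.12), did not pass. Gapdh, at 33.3 normalized counts in ShCTR, and Ppia, at 48.8, were low for genes that are abundant in most cells. Actb, Gapdh and Ppia have many processed pseudogenes, so how their reads were counted is uncertain.

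The cells of pair 1 differed from those of the other pairs whatever the hairpin, as 2 genes picked after their values were seen show. Ddit3, a stress-response gene, was at 19834.5 and 18837.4 normalized counts in the ShCTR and ShHuR libraries of pair 1 and at 614.7 to 1141.6 in the other 6 libraries. Ccl2 was at 445.5 and 604.8 in pair 1 and at 11740.3 to 32784 in the others. As a median over the list, inflammation genes were −1.34 and collagens 1.37 on the log2 scale in pair 1 against the mean of the other pairs. Those values average the ShCTR and ShHuR libraries of each pair. They therefore also hold the smaller response of pair 1 in both lists and are not a baseline of the controls alone.

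Pair 1 also moved less after knockdown. The slope of its log2 changes on the mean of the other pairs, across all tested genes, was 0.26, against 0.91, 1.29 and 0.86 in pairs 2, 3 and 4. For pairs 2 to 4 that mean includes pair 1, so the slopes do not give the relative size of the responses. The SD of the log2 changes over genes was 0.45 in pair 1 against 0.66, 0.85 and 0.64. In pair 1, 488 genes moved over 2-fold, against 1107, 1969 and 1124. The depth of ShHuR replicate 1 is argued against by the other pairs alone. With every library thinned to the same total, their lowest slope was 0.84. The slope of pair 1 stayed at 0.26, but ShHuR replicate 1 is the shallowest library and loses no reads by thinning. That unmoved slope therefore decides nothing. A different starting level is argued against as the whole cause, since among genes whose control level in pair 1 was within 1 log2 unit of the other controls the slope was 0.29 and the lowest of the others 0.81. Less complete knockdown may contribute, as pair 1 kept 11.5% of Elavl1: pair 4, with 7.7% left, had a slope of 0.86, below pairs 2 and 3, but the gap of 0.05 is smaller than the 0.39 between those 2 pairs, so this stays open. A different response of those cells was not tested.

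In limma with the block 12 of 26 collagens fell and 15 of 35 inflammation genes rose, and the gap between the list medians was 1.33 on the log2 scale (camera with an estimated correlation, adjusted p = 0.555 for each list). The lower depth of the ShHuR libraries is argued against, since the gap was 1.44 after thinning. Fewer fibroblast-like cells could account for the lower collagens and stay open: the 12 other members of the fibroblast list had a median of −0.54 (SE over members 0.15), 0.06 before rounding from the collagen median of −0.61, while the bound first written used Col1a1 and Col3a1 alone, top genes of the pattern, and decides nothing. Leukocyte RNA as the source of the higher inflammation genes stays open. The 3 markers tested had a median of 0.31 (SE over markers 0.12), below the inflammation median of 0.73 by more than that SE. This met the bound written beforehand against leukocyte RNA. Cd14 was at 0.42, Cd68 at 0.31 and Csf1r at −0.18. In pair 3, where the inflammation median was 0.65, Cd14 went from 606.3 to 528.5 and Cd68 from 39.3 to 21.9. Csf1r went the other way there, from 3.7 to 12.5. These markers cannot decide, because 5 of 20 had a row, and Cd14, at 309.7 to 653.4 normalized counts in every library, would hide a small share. Csf1r lay at 12.5 or below in pairs 2 and 3. The 2 untested ones lay near the floor and moved apart: in 4 of 4 pairs Coro1a was lower in ShHuR, at 29 or below in every library, and Cd74 higher, at 13.2 or below. An effect of losing HuR is the hypothesis the design gives, and it stays open beside these.

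The hypothesis that transcripts described as HuR-bound fall together after knockdown was tested with camera and the block. The p was 0.332 and the direction was up, with a median of 0.11, so the test decides neither way. The list was written from general knowledge, holds genes of the inflammation and protease lists, and was not derived from binding in these cells.

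Other groupings of the libraries were fitted in the same way. Without the block the real grouping called 0 genes, a count that all 35 splits into 4 and 4 reach by construction, so the comparison says nothing about chance. The highest other split called 492 genes and set pairs 2 and 3 against pairs 1 and 4, while the 2 other splits that keep every pair together called 0. Of the same 35 splits, 20 gave at least the 4 lists of the real one, with up to 10 in another, but 27 of the 35 leave whole pairs on 1 side and carry the differences between pairs. Among the 8 that part all 4 pairs, as the real one does, 2 gave as many and the highest other gave 9, and 8 splits are too few for a share under 0.05. With the block there are 8 ways to swap libraries within pairs, too few for a share under 0.05. The real one called 1802 genes, 1 of 8 with as many, and the highest other called 0. For lists, 2 of 8 gave as many as the real 7, and the highest other, which exchanged the labels of pair 1, gave 9.

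The authors' deposited table gives Elavl1 a log2 value of −1.82 and Mmp13 1.17, where limma gave −4.84 and 3.17. DESeq2 was run on the recovered reads with and without the block and with and without a prior on fold changes. The version with both called 2076 genes, correlated with the log2 values of the authors' deposited table at 0.9925 across genes, which are not independent replicates, and gave Elavl1 −1.79. The version with the block and no prior gave −4.88. The median absolute difference from the deposited log2 values was 0.000594 with both. It was 0.0216 with the block alone, 0.0295 with the prior alone and 0.0358 with neither. Of these versions the one with both was closest, but the model behind the deposited table is not given in the sources used here.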
